A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

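The series holds 8 sample files from 6 samples and 1 annotation file of the series. Total RNA was extracted with hot phenol, and mature rRNA was gel-purified for 3 samples, per the labels. The RNA was degraded to fragments of 20 to 40 nucleotides, joined to RNA adapters with a tRNA ligase lacking kinase activity, copied to cDNA and sequenced on an Ion semiconductor instrument, per the labels and the design text. Adapter removal with cutadapt 1.2 and alignment with Bowtie2 2.1.0 are named in the submitters' processing notes. The genome build, mapping options and treatment of reads with several alignments are not given in the sources used here. Reads that match several rDNA copies all measure the same rRNA, and differences between copies were not analysed here.

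Each sample file held 6 tracks in 1 column: read-end counts of the RNA 3' ends, counts of the 5' ends and counts of both, all deposited by the authors without normalization, and 3 scores computed by the authors, of which Score A was used for comparison and Score B and a pseudouridine score were not used here. Score A is a different statistic from the score computed here, so that their values are not on 1 scale. The third track equalled the sum of the first and the second at all 5196 mature rRNA positions in each library, and the combined knock-in file equalled run 1 plus run 2 at all 5196 positions. Both kinds of end were already placed on the same bond, per the file headers and values. In 7 of the 8 files only the 18S and 25S rRNA were covered. The knock-in mature LSU file covered the 35S precursor, and its headers record a data handling version of its own that allowed no errors in the first 3 nucleotides from the RNA end. Whether the other files were made with that filter is not given in the sources used here, so that differences in read handling cannot be separated from other differences involving this library. The knock-in whole-cell sample came as separate first and second files, called runs here and counted as 1 sample. Whether they are sequencing runs or separate library preparations is not given in the sources used here.

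From the counts a methylation score was computed as 1 minus the read ends at a position divided by the mean of its left and right neighbours, with 6 positions on each side weighted from 1 down to 0.5 in steps of 0.1, and negative values were set to 0. A score below 1 at a methylated position measures protection relative to neighbours, and uneven cleavage, ligation or alignment of the neighbours moves it as well. Intervals of 95% came from 2000 Poisson resamples of the counts. A resample of 0 counts stays at 0, so sites with 0 read ends have intervals without width, and the limit of 3 counts is given for them where they are named. Shares of read ends have 95% Wilson intervals. A known site counted as detected above the 99th percentile of unlisted positions of the same library and subunit, and as low-scoring with an upper bound below 0.8. Positions outside the lists counted as high with a score of at least 0.8 and a mean flanking count of at least 10.

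Comparisons between libraries used the score difference, without a p-value. A site counted as higher or lower when the 95% counting interval of the difference excluded 0 and the difference exceeded 2 SD of the difference between the knock-in whole-cell runs over the known sites of the subunit. The knock-in mature LSU library was compared with the wild-type LSU library, and the whole-cell runs with the knock-out. The knock-out was compared with both wild-type libraries and with the whole-cell runs, and chromatin-associated RNA with both wild-type libraries. Median scores of pseudouridines and base modifications were set against 10000 random lists of unlisted positions matched on deciles of the flanking count. Random lists planned for the differences at known sites are not reported, because unlisted positions have scores near 0, where they can hardly be lower, and known sites have scores near 1.

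The lists held 55 ribose methylation sites (37 LSU, 18 SSU), 43 pseudouridines and 12 base modifications and came from general knowledge of yeast rRNA. Of the 55 ribose sites 54 were in the deposited annotation, as were all 43 pseudouridines and 9 of the 12 base modifications. Guide names were matched by symbol to the R64 gene table for 39 of 42 guide RNAs, and the table served only for names and gene order. Matching of random lists on the base, and a check of listed positions against the reference base, were planned but need a sequence, which was not used here. The flanking count and the deposited annotation took their place. The lists, the criteria, the rule for named sites and most alternatives were fixed before the data were examined. Alternatives chosen after that were the run-to-run SD without LSU-Um2421, the flanks without LSU-U2954, run 1 as the reference of the knock-out, the subtraction of a uniform background, and the spread (SD of the run difference divided by the square root of 2) by which a median counted as moved. Named sites were the targets, the sites sharing a guide or plasmid with the knock-out, known sites within 50 nucleotides of a target, the 5 lowest and 5 highest known sites per subunit in wild type, the 10 largest losses and up to 5 largest gains among sites counted as different, each base modification, and up to 5 shared high-scoring unlisted positions per subunit.

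The computation was checked on simulated data. Poisson counts were drawn from the wild-type LSU means with 200 unlisted positions given known protection. A protected share of 0.3 gave a median score of 0.299 over 67 positions, 0.6 gave 0.605 over 67 and 0.9 gave 0.902 over 66. For the knock-in against wild type, simulated losses of 0.5 were called at 66 of 66 positions, losses of 0.2 at 0 of 67 and unchanged positions at 0 of 67. For the knock-out the counts were 64 of 66, 3 of 67 and 0 of 67, and for chromatin 66 of 66, 0 of 67 and 0 of 67. A loss of 0.2 lies under the LSU limit of 0.329, so that few calls were possible there. The simulated counts were set from the same weighted neighbours that the score divides by, so the scores return the protected share by construction. Both libraries started from a protected share of 0.95, without variation in protection between libraries. The check therefore does not measure the effect of uneven cleavage or of differences between libraries.

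Alternatives changed the flanks (2 positions, equal weights, median, known sites left out), the ends counted, the setting of negative values to 0, the minimum flanking count (50), the limits, the depth (thinning to the shallower library) and the reference library. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.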

Results

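Ribose methylation of ribosomal RNA was mapped in the yeast Saccharomyces cerevisiae by RiboMeth-seq. In this assay RNA is broken by alkali, the fragments are cloned through adapters joined by a tRNA ligase, and the ends of the sequenced fragments are counted at each phosphodiester bond. A methyl group on the ribose 2'-oxygen protects the bond from cleavage, so that a methylated nucleotide lacks read ends compared with its neighbours. Nearly all such sites in yeast are chosen by box C/D snoRNAs, small nucleolar RNAs that pair with the rRNA and guide the methyltransferase to 1 nucleotide. The 6 samples formed 6 groups with 1 sample each: gel-purified large subunit (LSU, 25S) rRNA of the wild-type strain BY4741, gel-purified small subunit (SSU, 18S) rRNA of the same strain, whole-cell RNA and gel-purified LSU rRNA of a knock-in strain (YWD680), whole-cell RNA of a knock-out strain (YWD486), and chromatin-associated RNA of BY4741. There were no biological replicates, so no p-value was calculated between groups. The only repeat measurement was a pair of data files of the knock-in whole-cell sample, called runs below although the labels do not say at which step they were separated. The counting intervals below assume independent reads and cover no variation between samples. Reads without molecular identifiers are not independent molecules, so that these intervals can be too narrow even for counting error.

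Depth differed widely between libraries. The wild-type LSU library held 1229170 read ends on LSU rRNA, and the wild-type SSU library held 283160 on SSU rRNA. In the knock-in mature LSU library 1197181 read ends lay on LSU rRNA. The combined knock-in whole-cell runs gave 734670 on LSU and 517732 on SSU rRNA, and the knock-out gave 214862 and 214756. Chromatin-associated RNA was the deepest library, with 18489246 read ends on LSU and 9790438 on SSU rRNA. The median LSU position had 333 read ends in the wild-type LSU library, 51 in the knock-out and 3883 in the chromatin library. Both rRNAs lie on the minus strand of chromosome XII, the 25S rRNA from 460923 to 464318 and the 18S rRNA from 465070 to 466869, in the coordinates of the deposited files, whose genome build is not given in the sources used here. All sites are non-coding rRNA positions counted from the 5' end of each mature rRNA.

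The first comparison asked whether positions known to be methylated stood apart from other positions in mature wild-type rRNA. They did so at almost every site. Of 37 known LSU sites, 36 scored above the 99th percentile of unlisted LSU positions, and all 18 known SSU sites scored above that of unlisted SSU positions. The median score was 0.975 at the known LSU sites and 0.960 at the known SSU sites, against 0.0324 and 0.0354 at 3307 and 1751 unlisted positions. The score is the share of read ends missing at a position relative to its neighbours, and it approaches 1 for full protection.

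Among LSU sites the highest scores were found at the adjacent pair LSU-Am2280 and LSU-Am2281, both guided by snR13, which had 0 read ends in wild type. With the 3 counts that a count of 0 allows, their scores would be 0.976 and 0.972. LSU-Um2417 (snR66) scored 0.995, LSU-Am2946 (snR71) 0.992 and LSU-Cm2337 (snR64) 0.992. In the SSU the 5 highest scores were 0.987 at SSU-Gm1428 (snR56), 0.986 at SSU-Am28 (snR74), 0.985 at SSU-Am541 (snR41), 0.985 at SSU-Cm1007 (snR79) and 0.982 at SSU-Gm1271 (snR40). The area under the ROC curve for known against unlisted positions was 0.999 in the LSU and 1.00 in the SSU, as a description across positions, which are not replicates. SSU-Gm562 was absent from the deposited annotation of modifications. It scored 0.922 (95% interval 0.873 to 0.965) in the wild-type SSU library and 0.956 in the knock-out. The authors' deposited Score A at this position, a different statistic, was 0.788 in the wild-type SSU library. LSU-Gm2395, a predicted site listed separately, scored 0 in wild type with 658 read ends.

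**Figure D1:**
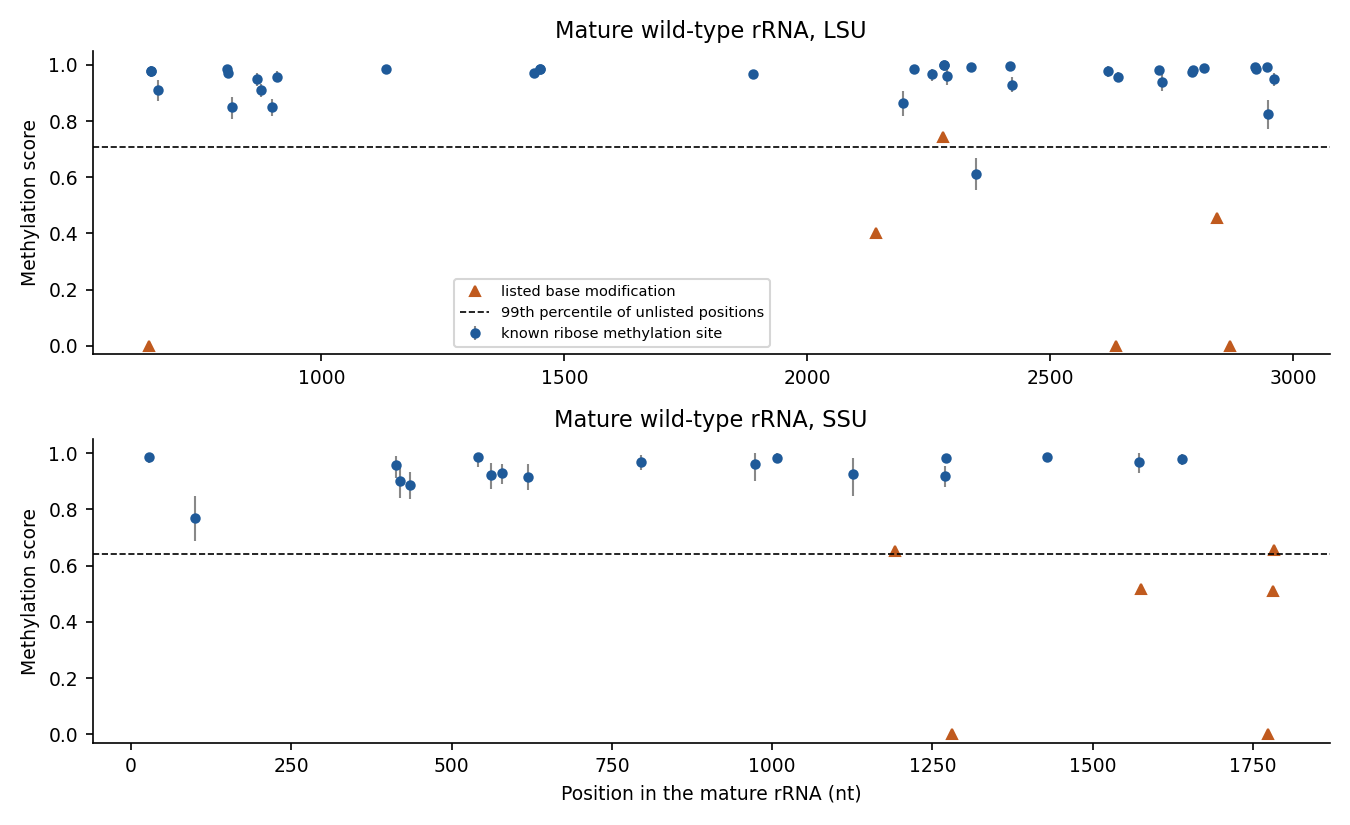
Methylation score (y axis, no unit) of known ribose methylation sites (circles, with 95% counting intervals) and listed base modifications (triangles) against position in nucleotides (x axis) in mature wild-type LSU and SSU rRNA. The dashed line is the 99th percentile of unlisted positions (0.707 in the LSU, 0.642 in the SSU), and 36 of 37 LSU sites and 18 of 18 SSU sites lie above it.

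Partial protection in mature wild-type rRNA was found at 1 of the 55 known sites under the criterion of an upper bound below 0.8. This was LSU-Um2347 (snR65), which scored 0.612 (95% interval 0.553 to 0.668) with 191 read ends and was also the LSU site below the detection limit. It was likewise the LSU site with the second-lowest score in the knock-in mature LSU library (0.344) and scored 0.454 in the knock-out and 0.475 in the chromatin library. SSU-Am100 (snR51) had the lowest SSU score, 0.771, with an interval of 0.689 to 0.849 that reached past 0.8. The next lowest LSU sites were LSU-Cm2948 (snR69) at 0.825, LSU-Um898 (snR40) at 0.849, LSU-Am817 (snR60) at 0.849 and LSU-Cm2197 (snR76) at 0.864. In the SSU they were SSU-Am436 (snR87) at 0.886, SSU-Am420 (snR52) at 0.902, SSU-Am619 (snR47) at 0.917 and SSU-Um1269 (snR55) at 0.920. With a limit of 0.9 the count was 5, and with 2 flanking positions on each side it was 2.

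The knock-in strain carries a plasmid with an artificial snoRNA directed at LSU-U2954, at position 461365 of chromosome XII, and the comparison asked whether this position gained a methyl group and whether other sites changed. LSU-U2954 rose from a score of 0.376 (0.280 to 0.467) in wild-type mature LSU rRNA to 0.924 (0.891 to 0.954) in the knock-in, a difference of 0.548 (0.449 to 0.648). The read ends at this bond numbered 181 in wild type and 22 in the knock-in. Both whole-cell runs of the knock-in gave 0.894, whereas the knock-out and the chromatin library, which lack the artificial guide, gave 0. The equal values of the runs are not a precise repeat. Run 1 had 2 read ends at this bond and a mean flanking count of 19, and run 2 had 15 and 129. The differences from wild type were 0.518 (0.315 to 0.674) in run 1 and 0.519 (0.409 to 0.623) in run 2. The authors' deposited Score A at LSU-U2954 was 0 in wild type, 0.656 in the knock-in mature LSU library and 0.515 in the combined whole-cell runs (0.683 in run 1 and 0.405 in run 2). Being a different statistic, it is not a second estimate of the same protected share. A site was counted as different when the counting interval of the difference excluded 0 and the difference exceeded 0.329, which is 2 SD of the difference between the whole-cell runs over LSU sites. LSU-U2954 passed both criteria, but its difference was smaller than the largest difference between the runs at any LSU site, 0.872 at LSU-Um2421.

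Among the 37 known LSU sites, 2 fell in the knock-in mature LSU rRNA and 0 rose. LSU-Am876 (snR72) fell from 0.911 to 0.313, with 49 read ends in wild type and 611 in the knock-in. LSU-Gm867 (snR50), 9 nucleotides away, fell from 0.949 to 0.549. The differences were -0.598 at LSU-Am876 and -0.400 at LSU-Gm867, against -0.672 and -0.589 with 3' ends alone and -0.303 and -0.172 with 5' ends alone. The call at LSU-Gm867 was lost in 8 of 16 alternatives, among them 5' ends alone, flanks of 2 positions (-0.336) and the knock-out as reference (-0.261). The unlisted position LSU-862, named after its values were seen, scored 0.882 in wild type and 0.506 in the same knock-in library. In the combined whole-cell runs of the knock-in LSU-Am876 scored 0.755 and LSU-Gm867 0.823, against 0.808 and 0.810 in the knock-out. Neither site was called lower in either whole-cell run against wild type. Both losses lay under the largest difference between the runs, so that the count was 0 with that limit. The header of the mature knock-in file records read handling that the other files do not state, and neither difference has a replicate check.

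Around the target, the 5 known sites within 50 nucleotides had a median difference of -0.163, against -0.0663 over all 37 sites, and none passed the limit in mature LSU rRNA. LSU-Am2946 scored 0.992 in wild type and 0.754 in the knock-in. LSU-Cm2948 had 0.825 and 0.649, and LSU-Cm2959 (snR73) scored 0.787 in the knock-in, a difference of -0.163. The remaining nearby sites, LSU-Um2921 (snR52) and LSU-Gm2922, the site of the enzyme Spb1, differed by -0.0231 and -0.0215. Against the knock-out, which is also whole-cell RNA, LSU-Cm2948 fell in the combined whole-cell runs, from 0.967 in the knock-out, with 1 read end, to 0.588, and LSU-Am2946 scored 0.880. Against wild type the difference at LSU-Cm2948 in the combined runs was -0.237, and 0 of the 5 nearby sites was called. The knock-out had 0 read ends at LSU-Am2946, and the 3 counts that this allows would give 0.884. In the comparison with the knock-out (0.444), LSU-Um2421 was called lower in the combined runs (0.0276) and in run 2 (0) but higher in run 1 (0.872), and LSU-Gm2619, the target of the knock-out, was higher in the knock-in. In the SSU, SSU-Um578 (snR77) fell from 0.990 to 0.778 and SSU-Am420 from 0.903 to 0.710. The combined runs differed from each other by 0.211 at SSU-Um578, against a difference of -0.212 from the knock-out. The counting interval lay below 0 at 31 of 37 LSU sites in mature rRNA. With LSU-Um2421 left out of the run-to-run SD, a limit of 0.164 chosen after the data had been examined, 9 sites were lower in mature rRNA, LSU-Am2946 and LSU-Cm2948 among them.

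**Figure D2:**
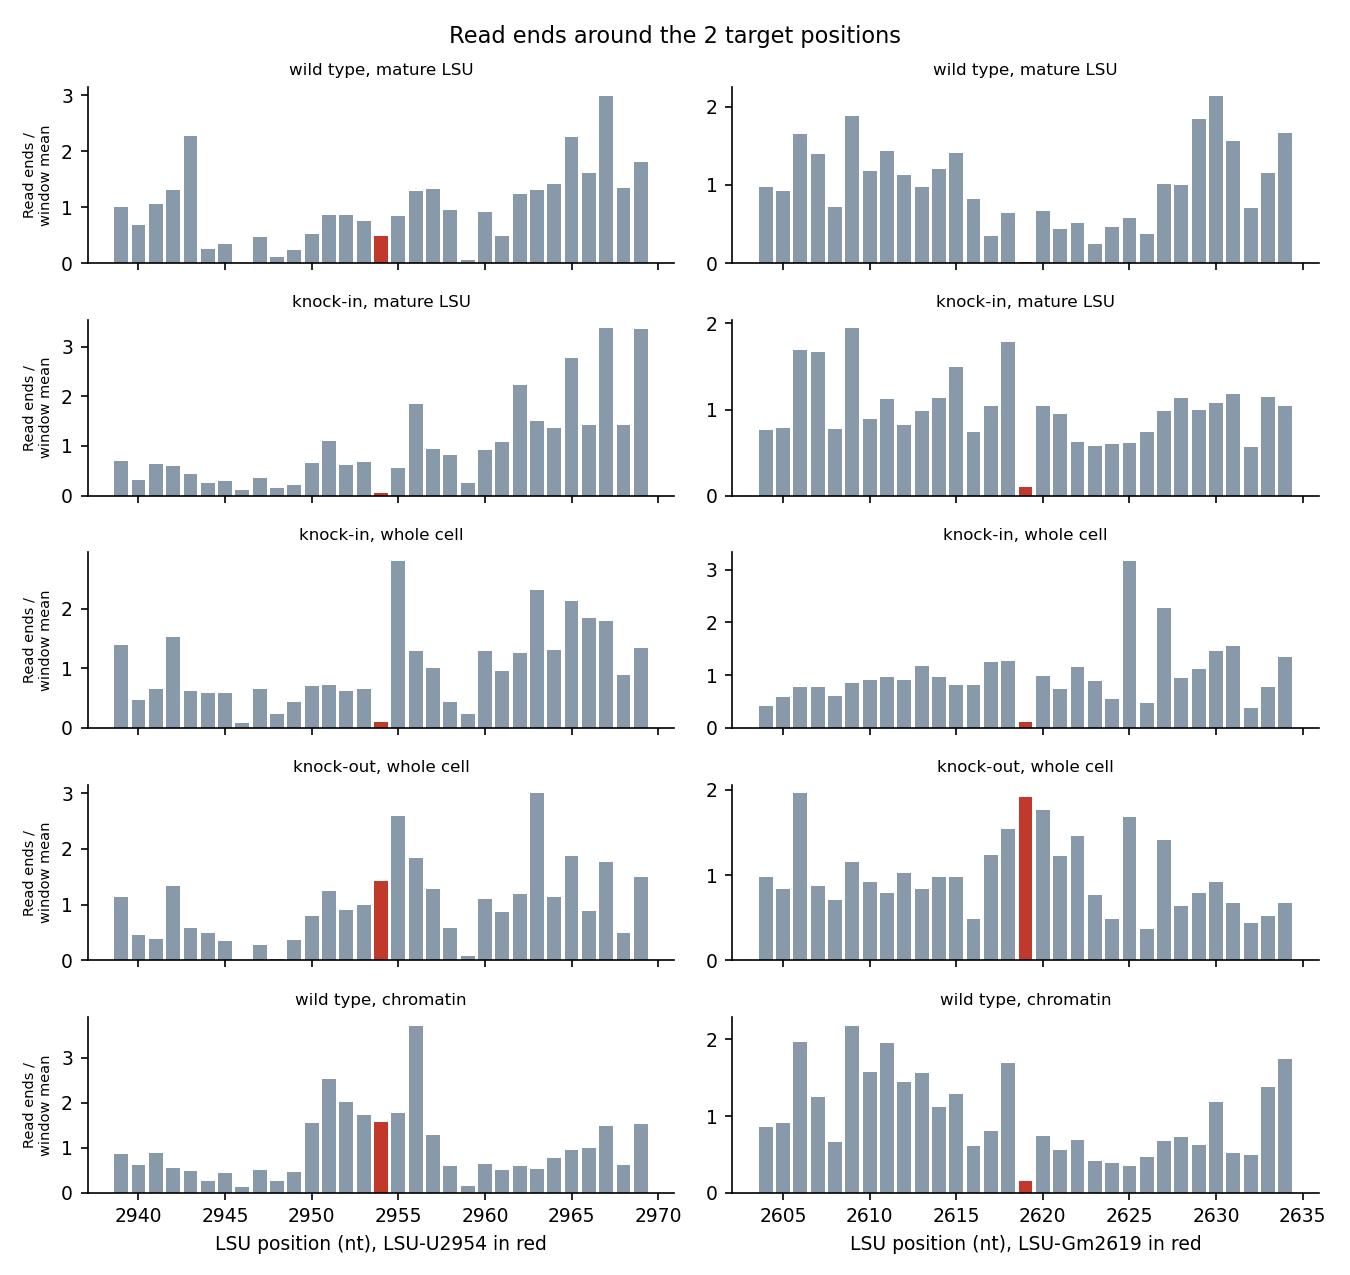
Read ends per position divided by the window mean (y axis, no unit) at 31 LSU positions (x axis, nucleotides) around LSU-U2954 (left) and LSU-Gm2619 (right) in 5 libraries, with the target bar in red. The red bar is low at LSU-U2954 in the knock-in libraries (22 and 17 read ends) and at LSU-Gm2619 in every library except the knock-out, which has 114 read ends there.

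The knock-out strain carries the region of snR67 and snR53, genes that neighbour each other in the R64 gene table, with 1 substitution that prevents methylation at LSU-G2619 (position 461700 of chromosome XII). The comparison asked whether this methylation was lost and others kept. LSU-Gm2619 fell from 0.978 (0.957 to 0.996) in wild-type mature LSU rRNA to 0 in the knock-out, where 114 read ends stood at the bond against a mean of 66.8 at its neighbours. Against the combined knock-in whole-cell runs, with a score of 0.889, the loss was -0.889. The other site guided by snR67, LSU-Um2724, scored 0.981 in wild type and 0.914 in the knock-out, a difference whose interval of -0.214 to 0.0273 held 0. At SSU-Am796, guided by snR53, the scores were 0.970 and 0.948. The known site nearest to the target, LSU-Am2640 (snR68), scored 0.958 and 0.945.

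Of the other 36 known LSU sites, 1 was lower in the knock-out than in wild type and 0 were higher, and 0 of 18 SSU sites was lower. The median difference was -0.00044 over these LSU sites and 0.00301 over the SSU sites. The lower site was LSU-Um2421 (snR78), at 0.444 against 0.930, with 27 read ends in the knock-out. It scored 0.872 in 1 knock-in whole-cell run and 0 in the other, and with the combined knock-in runs as the reference its difference was 0.417, in the opposite direction. Of its 27 read ends 25 were 3' ends, and with 5' ends alone the difference was -0.0628. LSU-U2954, unmodified in both strains, scored 0.376 in wild type and 0 in the knock-out, a difference past both criteria at a position that neither strain is labelled to modify. The whole-cell knock-out was compared with gel-purified wild-type rRNA, so that strain and RNA type differed together.

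**Figure D3:**
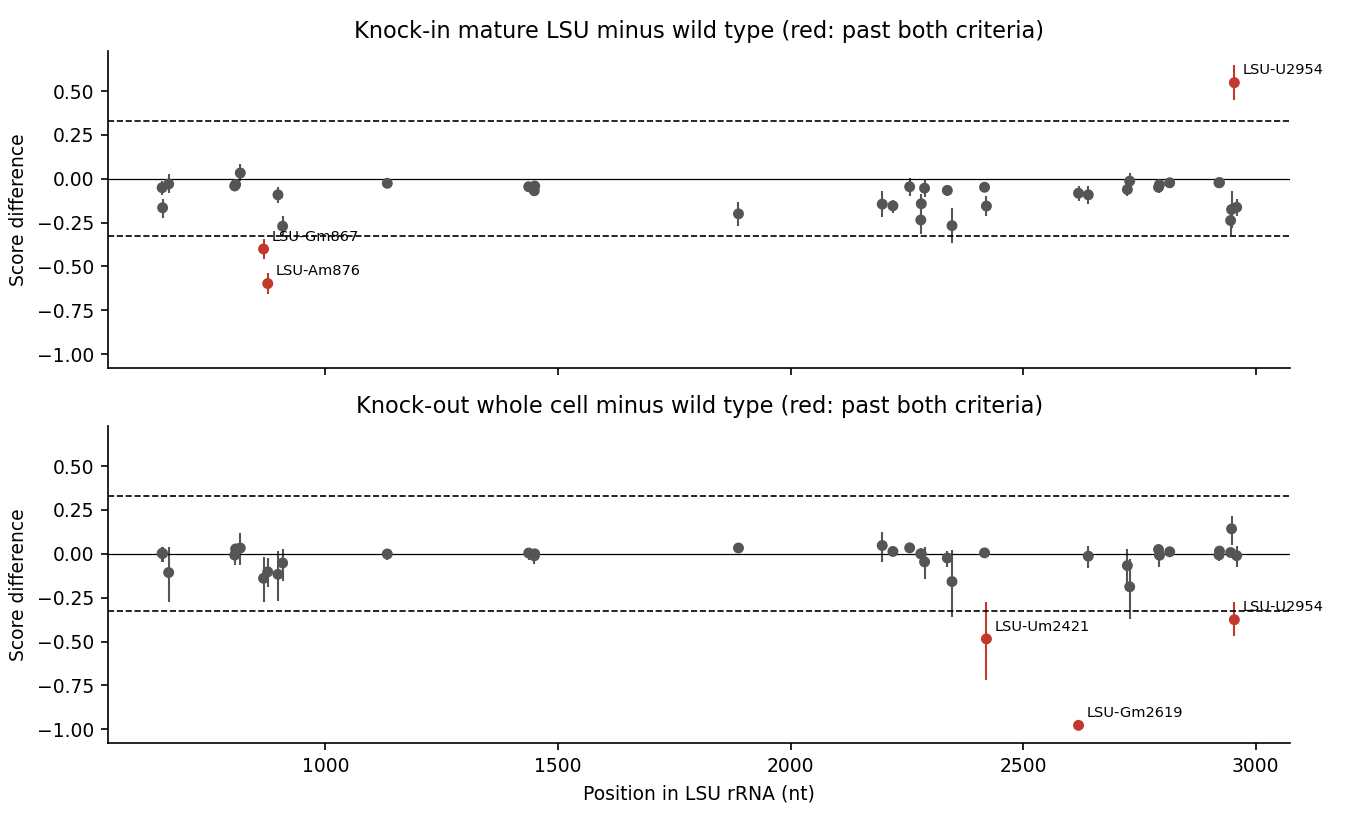
Score difference from wild-type mature LSU rRNA (y axis, no unit) at the known LSU sites and LSU-U2954 against position (x axis, nucleotides) for the knock-in mature LSU library (top) and the knock-out whole-cell library (bottom), with 95% counting intervals as vertical lines. Dashed lines mark the limit of 0.329 in both directions, and sites past both criteria are red. In the knock-in these are LSU-U2954 at 0.548, LSU-Am876 at -0.598 and LSU-Gm867 at -0.400. In the knock-out they are LSU-Gm2619 at -0.978, LSU-Um2421 at -0.485 and LSU-U2954 at -0.376.

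Chromatin-associated RNA holds nascent and recently made rRNA, and its comparison with mature rRNA of the same strain asked which methylations were less complete there. Scores were lower across both subunits, unevenly between sites. The read ends themselves were more uneven in chromatin than in its references. The coefficient of variation between positions was 0.986 against 0.570 in the LSU and 1.00 against 0.555 in the SSU. Uneven neighbours move the score, and their part in these differences was not tested. LSU scores were lower in value at 36 of 37 known sites, with a median difference of -0.137, and SSU scores at 18 of 18 sites, with a median of -0.085. With the combined knock-in whole-cell runs in place of gel-purified wild-type rRNA as the reference, the medians were -0.0857 and -0.0499, and with the knock-out -0.130 and -0.101. Scores near 1 in mature rRNA can hardly be exceeded, so that the direction alone carries little weight. The exception in the LSU was LSU-Cm2197, at 0.920 in chromatin and 0.864 in mature rRNA. Lower values were not limited to chromatin. Against the same wild-type LSU library, the knock-in mature LSU library was lower in value at 36 of 37 sites (median -0.0663). The combined knock-in whole-cell runs were lower at 35 of 37 (median -0.0392) and the knock-out at 19 of 37 (median -0.00088).

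In the LSU, 3 sites fell by more than the limit. LSU-Gm2922, which the enzyme Spb1 methylates without a snoRNA, fell from 0.984 to 0.430 (0.411 to 0.448), with 3791 read ends. Its neighbour LSU-Um2921, guided by snR52, had 0.991 and 0.843. LSU-Gm867 fell from 0.949 to 0.461 and LSU-Am2256 (snR63) from 0.966 to 0.602. The differences at LSU-Gm2922, LSU-Gm867 and LSU-Am2256 were -0.554, -0.488 and -0.364. They depended on the ends counted: with 3' ends alone they were -0.607, -0.255 and -0.123, the last 2 no longer called, and with 5' ends alone -0.460, -0.644 and -0.443. With flanks of 2 positions they were -0.825, -0.374 and -0.316, the last no longer called. The call at LSU-Am2256 was also lost without setting negative scores to 0, where the limit was higher and 2 LSU sites were lower. LSU-U2954, which is unmodified in this strain, scored 0.376 in mature rRNA and 0 in chromatin, a difference of -0.376 that also passed both criteria. The unlisted position LSU-862 scored 0.554 in chromatin and 0.882 in mature rRNA. Among the 36 snoRNA-guided LSU sites the median difference was -0.135. By region it was -0.149 over the 14 LSU sites up to position 1500, -0.133 over the 23 sites beyond it and -0.158 over the 6 sites from position 2800 on, around the peptidyl transferase centre. In the SSU, 2 sites fell: SSU-Am100 from 0.771 to 0.485 and SSU-Am541 from 0.985 to 0.820. The difference at SSU-Am541, -0.165, was close to the SSU limit of 0.151, and SSU-Am100 was the 1 SSU site called in 5 of 13 alternatives, including 3' ends alone and flanks of 2 positions. SSU-Cm414, guided by U14, a snoRNA also needed for processing of the precursor, scored 0.959 in mature rRNA and 0.839 in chromatin. The LSU count was 13 with LSU-Um2421 left out of the run-to-run SD, and 0 with the largest run difference as the limit.

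**Figure D4:**
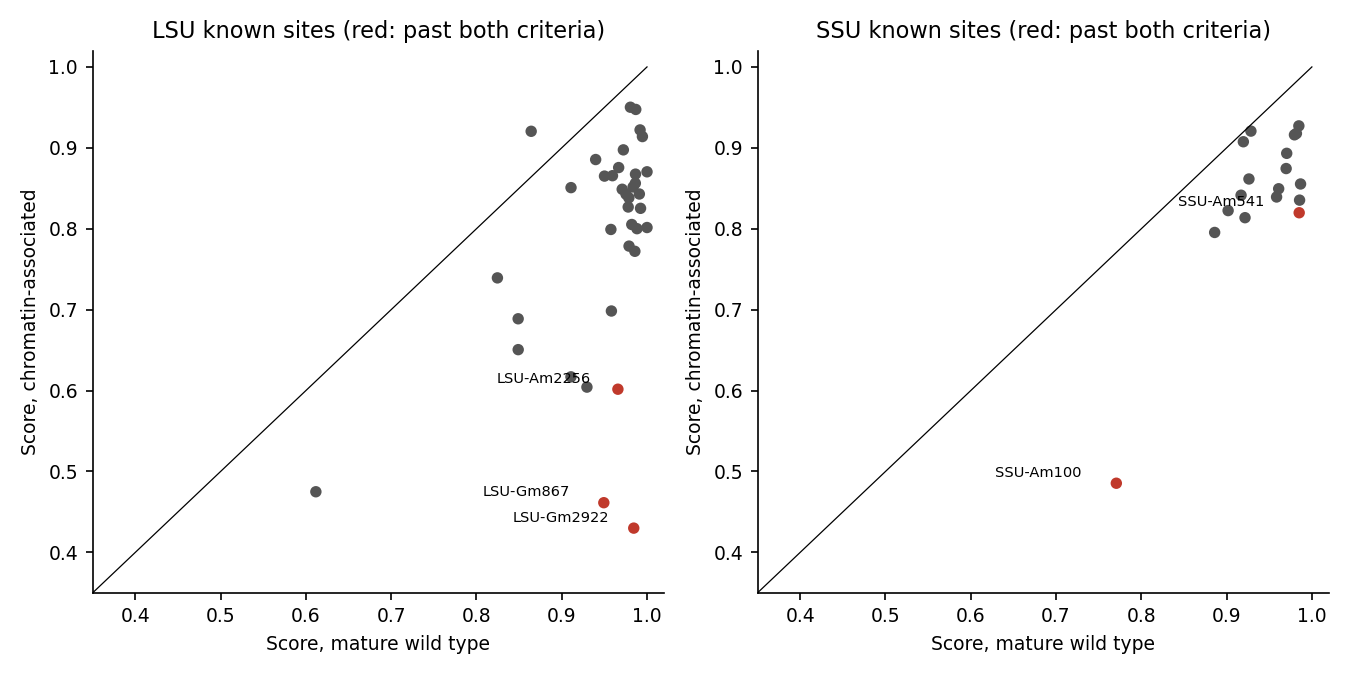
Methylation score in chromatin-associated RNA (y axis) against mature wild-type rRNA (x axis), both without unit, for 37 LSU and 18 SSU known sites, 1 point per site, with equality as the line. Red points passed both criteria, and LSU-Gm2922 is the lowest LSU point at 0.430 in chromatin.

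Modifications other than ribose methylation were examined at the same bonds. Pseudouridine positions, where the uridine base is attached through carbon, scored well above unlisted positions. The median over 30 LSU pseudouridines was 0.690 and over 13 SSU pseudouridines 0.577, above all of 10000 random lists in both subunits. The share of unlisted positions at or above these medians was 1.30% in the LSU and 1.71% in the SSU. LSU-Psi2129 reached 0.896, LSU-Psi990 0.872 and SSU-Psi1181 0.836, and 14 of the 30 LSU pseudouridines and 3 of the 13 SSU ones passed the limit used for detection. These pseudouridines were named after their values were seen. With 3' ends alone the LSU median was 0.921 and with 5' ends alone 0.493, whereas known LSU ribose sites had 0.969 and 0.978. In chromatin the pseudouridine medians were 0.732 in the LSU and 0.709 in the SSU. The random lists were matched on flanking count and not on base, since no sequence was used here.

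Listed base modifications varied between positions. In mature wild-type rRNA the SSU median of 0.514 over 6 positions was matched or exceeded by 1 of 10000 random lists. The LSU median of 0.201 over 6 positions was matched or exceeded by 1805. SSU-m62A1781 and SSU-m62A1782 are adjacent and share flanking positions, so that their scores are not independent. In the SSU, SSU-m62A1782 scored 0.655, SSU-m1acp3Psi1191 0.652, SSU-m7G1575 0.517 and SSU-m62A1781 0.511, while SSU-ac4C1280 and SSU-ac4C1773 scored 0. In the LSU, LSU-m5C2278 scored 0.742, LSU-m3U2843 0.454 and LSU-m1A2142 0.402, and LSU-m1A645, LSU-m3U2634 and LSU-m5C2870 scored 0. LSU-m5C2278 lies next to the highest-scoring LSU sites, within 3 nucleotides of LSU-Am2281. In the chromatin library SSU-m62A1781 scored 0 and SSU-m62A1782 0.490, and LSU-m3U2634 scored 0.645. The contrast between the subunits was reversed in chromatin. There the SSU median of 0.372 was matched or exceeded by 758 of 10000 random lists and the LSU median of 0.4996 by 147. With 5' ends alone the base modification medians in mature wild-type rRNA were 0 in the LSU and 0.0255 in the SSU.

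Outside the lists few positions were strongly protected. In mature wild-type rRNA 9 LSU positions and 1 SSU position scored at least 0.8, against 40 and 15 in the chromatin library, 18 and 7 in the knock-out and 28 and 21 in the combined knock-in whole-cell runs (56 and 28 in run 1, 88 and 55 in run 2). In the knock-in mature LSU library 8 LSU positions did. The position LSU-234, at 464085 on chromosome XII, was the 1 LSU position at or above 0.8 in all libraries covering the LSU, and 0 SSU positions were shared. LSU-234 scored 0.899 (0.867 to 0.927) in wild-type mature rRNA, 0.924 in the knock-in mature LSU library, 0.808 (0.719 to 0.885) in the knock-out and 0.926 (0.919 to 0.932) in chromatin. With a limit of 0.9 the shared count was 0.

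Repeatability could be measured only between the runs of the knock-in whole-cell sample. Over known sites the SD of the run difference was 0.164 in the LSU and 0.0755 in the SSU. A single site, LSU-Um2421, contributed most of the LSU value: it scored 0.872 in run 1 with 10 read ends and 0 in run 2 with 210, of which 209 were 3' ends. Without it the LSU SD was 0.0819. The largest SSU difference was 0.211, at SSU-Um578. Across all positions Pearson's r of the score was 0.339 over 3384 LSU positions and 0.331 over 1788 SSU positions, with Spearman's rho of 0.329 and 0.316. Read-end counts also correlated weakly, with Pearson's r of log counts of 0.254 in the LSU and 0.334 in the SSU and Spearman's rho of 0.215 and 0.284. The median LSU position had 62 read ends in run 1 and 98 in run 2, so that the runs differed by more than counting error of independent reads. At which step they were separated stays unknown. Positions are not independent replicates. Read ends were also spread more unevenly in run 2, with a coefficient of variation between LSU positions of 1.64 against 0.704 in run 1 and 0.570 in the wild-type LSU library.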

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

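All tests in this part were chosen after the results or the scores of the sites involved had been seen. Read ends outside the rRNA that each purified sample was meant to hold exceeded the limit of 3 that a count of 0 allows. In the knock-in mature LSU library, the precursor segments held 1041 read ends in the 5' external transcribed spacer, 183 in the first and 163 in the second internal transcribed spacer and 7 in the 3' external spacer, and the 5.8S rRNA held 226. Per position this was 0.422%, 0.144%, 0.199% and 0.00941% of the 25S mean for the spacers in that order. With 12 positions left out at each end the 3' external spacer held 0%, so that its 7 read ends lay at its edges. SSU rRNA held 8429 read ends in the knock-in mature LSU library and 30674 in the wild-type LSU library, or 0.699% and 2.43% of their read ends. LSU rRNA held 70381 read ends, or 19.9%, in the wild-type SSU library.

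The losses at LSU-Gm867 and LSU-Am876 in the knock-in mature LSU library were larger than counting error of independent reads, since the higher of the upper bounds of their differences was -0.345. A changed read-end pattern along this stretch, rather than at the methylated bonds alone, stays open: the neighbouring unlisted position LSU-862 also differed, by -0.376 (-0.444 to -0.306), but it was picked after its values were seen, which decides nothing. Within the knock-in strain the losses were not shared in full. LSU-Am876 scored 0.755 in the combined whole-cell runs and 0.313 in the mature LSU library, and LSU-Gm867 0.823 and 0.549. These values argue against a strain difference as the whole cause, since it would act in both libraries. RNA type differed between these libraries and read handling may have differed, so that these cannot be told apart. In the whole-cell runs the differences from wild type at these sites lay between -0.318 and -0.116. None was past the limit, although 3 of the 4 intervals lay below 0, so that a smaller biological difference between the strains stays open. Lower scores at these sites were not particular to the knock-in strain. Against the same wild-type LSU library, wild-type chromatin differed by -0.488 at LSU-Gm867 and -0.294 at LSU-Am876. The knock-out differed by -0.140 and -0.103. All of these intervals lay below 0, and only LSU-Gm867 in chromatin passed the limit.

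The lower scores near LSU-U2954 in the knock-in were not due only to the newly protected target inside the flanking window. With the target left out of the flanks, the mean difference at LSU-Cm2948 and LSU-Cm2959 was -0.154 (-0.210 to -0.100), against -0.169 with it. Lower scores across the whole knock-in library remain a possible explanation, since 6.1% of 10000 random lists of 5 other known LSU sites had a median as low as the -0.163 of the 5 nearby sites. A biological effect of the artificial snoRNA stays open, as untested.

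The lower scores in chromatin-associated rRNA were not removed by subtracting the largest uniform background possible, the lowest count at a known site. The median difference was then -0.106 (95% bootstrap interval over sites -0.131 to -0.0597) in the LSU and -0.0287 (-0.0523 to -0.0132) in the SSU, so that a background of this kind could account for part of the loss, the larger part in the SSU. These intervals treat sites as repeats and do not cover variation between libraries. The combined knock-in whole-cell runs and the knock-out differed by a median of -0.0492 over the SSU sites. In the SSU the remainder therefore does not exclude a background as the whole cause. In the LSU, the knock-in mature LSU library differed from the same wild-type library by a median of -0.0663, inside the interval of the remainder. The LSU remainder of -0.106 was larger than this, but differences between libraries could make up part of it. Depth was no cause in the LSU, where thinning left a median of -0.148 (-0.188 to -0.0954). Incomplete methylation of young rRNA, with late sites lowest, stays open: LSU-Gm2922, the site of the late-acting Spb1, ranked 1 by loss among 37 LSU sites, but this rank was known when the test was chosen. Its loss exceeded that of LSU-Gm867 in 12 of 14 alternatives (-0.607 against -0.255 with 3' ends alone), but not with 5' ends alone (-0.460 against -0.644) or with known sites left out of the flanks (-0.483 against -0.488). The changed limits, the unclipped score and the minimum flanking count left both differences as they were. Those alternatives could not alter the order and add nothing to this count.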

How the results depend on the processing

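Across all alternatives, 178 values of the results that answer a comparison stayed within the tolerance, 1 was weaker and 46 moved. The tolerance was the same side of the limit for a call, a factor of 1.5 for a count and 1 run-to-run spread for a median, and an equal count need not hold the same sites: run 2 in place of the knock-in mature LSU library gave 2 lower sites, LSU-Um2347 and LSU-Um2421 in place of LSU-Gm867 and LSU-Am876. Among single named sites 144 were the same, 21 weaker, 5 stronger and 1 reversed. Alternatives that change only the limit cannot move a median, so that some values were unchanged by construction. The spread for a median was the SD of the run difference, 0.164 in the LSU and 0.0755 in the SSU, divided by the square root of 2. It was wide beside the chromatin medians of -0.137 and -0.085. A large part of such a median could be lost within the tolerance, so that an unchanged median is weak evidence of stability. The loss at LSU-Gm2619 in the knock-out kept its call in all 14 alternatives, with differences from -1.63 (score not clipped) to -0.889. The gain at LSU-U2954 kept its call in 15 of 16, from 0.457 to 0.924. It lost the call, with the same difference of 0.548, when the largest run difference was the limit, because that limit is higher. The count of detected known sites was lowest with 5' ends alone (43) and highest with a score limit of 0.5 (55), and the median LSU difference in chromatin stayed between -0.155 and -0.0857.

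Where no cause is given below, the cause was not tested. With flanks of 2 positions, 2 low-scoring sites were counted in wild type, 1 SSU site was lower in chromatin and 0 unlisted positions were shared by all libraries. With the median of the flanks, 6 LSU sites and 1 SSU site were lower in chromatin and 0 unlisted positions were shared.

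With 5' ends alone, 5 known LSU sites were lower in the knock-in, LSU-Gm867 not among them (-0.172), 14 in chromatin, and 2 in the knock-out besides its target LSU-Gm2619. The pseudouridine medians were 0.493 in the LSU and 0.469 in the SSU, the base modification medians 0 and 0.0255, and the LSU SD between runs 0.0909. This lower SD lowers the limit, so that more LSU calls were possible without larger losses. The median LSU difference in chromatin was -0.116 with 5' ends alone, against -0.137 with both ends. Of unlisted positions 92 were high in wild type and 14 were shared. With 3' ends alone, 5 sites were lower in the knock-in and 1 SSU site in chromatin. The pseudouridine medians were 0.921 and 0.659, the base modification medians 0.630 and 0.590, and the SSU SD between runs 0.121, with 176 unlisted positions high in wild type and 3 shared.

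Without setting negative scores to 0, 1 site was lower in the knock-in, because the SD between runs was 0.227 and the limit higher, while the difference at LSU-Gm867 remained -0.400. With a flanking count of at least 50, 0 other sites were lower in the knock-out, since LSU-Um2421 had a mean flanking count of 48 and was left out; it and LSU-Um2724 had no value here. Limits of 0.9 gave 5 low-scoring sites, 1 high unlisted position in wild type and 0 shared, which follows from the limit. With the largest run difference as the limit, the LSU counts were 0 in the knock-in, 0 in the knock-out besides its target and 0 in chromatin, with 1 SSU site lower in chromatin. With the SD taken without LSU-Um2421, chosen after the data were seen, they were 9, 2 (besides the target) and 13. Both follow from the height of the limit.

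With whole-cell run 1 in place of mature LSU rRNA, 0 sites were lower in the knock-in, and 1 with the combined runs or with the knock-out as reference. In the knock-out, the combined knock-in runs as reference gave 0 lower sites besides the target and 2 higher sites, and LSU-Um2421 was reversed to 0.417. With the knock-in mature LSU library or, chosen after the data were seen, run 1 as reference, 1 site was higher. With a uniform background subtracted from chromatin, chosen after the data were seen, 1 SSU site was lower and the median SSU difference was -0.0287.

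The median LSU position of the knock-out had 51 read ends, and in simulated data at its depth 64 of 66 losses of 0.5 were called, against 66 of 66 in the deeper knock-in mature LSU and chromatin libraries. Apart from the set losses, these simulations varied by counting error alone.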

Other observations

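The test in this part was chosen after the scores of its sites had been seen. LSU pseudouridine scores were lower in chromatin than in mature rRNA at 11 of 30 positions and SSU ones at 4 of 13, with median differences of 0.017 and 0.243, whereas the ribose sites had medians of -0.137 and -0.085. The medians of random lists of unlisted positions, matched to the pseudouridines on flanking count, were 0.0359 in mature and 0.138 in chromatin-associated LSU rRNA and 0.0376 and 0.127 in SSU rRNA. The difference between the lists was not tested.

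The hypothesis was that sites guided by the snoRNA genes SNR72 to SNR78, which follow one another in the R64 gene order, share their loss in chromatin-associated rRNA. The 5 LSU sites of this cluster had differences of -0.325 (LSU-Um2421), -0.294 (LSU-Am876), -0.0939 (LSU-Gm2288), -0.0851 (LSU-Cm2959) and 0.0563 (LSU-Cm2197). In 88.49% of random lists of 5 other LSU sites the median was as low as theirs, but a median over sites that differ in direction shows neither a shared loss nor its absence, so that the hypothesis stays undecided.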
